A study of Ovis aries with 2 samples.

How the data were processed

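Granulosa cells were scraped from follicles above 2.5 mm in diameter, and 5 µg of RNA per diet group went into a TruSeq library with 15 PCR cycles, per the labels' protocols. The labels assign 8 ewes to each group and do not state how many ewes contributed RNA to each library. Sequencing was on an Illumina HiSeq instrument. TopHat and Cuffdiff and the sheep build Oar_v3.1 are named per the submitters' processing notes, without versions. The annotation behind the transcript entries is not given in the sources used here.

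The deposited table has 1 line per transcript entry, 22881 in all. The authors' scaled read columns are a signal in which read counts were divided by 1 size factor per library, so that 1 read is worth 1.02 in the supplemented and 0.983 in the restricted library. Dividing by that step gave whole reads, within 0.02 of a read, for 98.9% of the 17628 entries above 0 in the supplemented library and 98.7% of 17364 in the restricted library. The FPKM columns were made by the authors, per the file headers, which name the unit and not the scaling. Log2 ratios of FPKM and of scaled reads differed by at most 0.00638, so both columns are on the same scaling. The authors' p-values and q-values are copied from the deposited table and were not recomputed. The authors' log2 fold change is supplemented over restricted, and it was checked against the FPKM columns. Columns were assigned to libraries by the sample descriptions, which name the feed levels. The 10 most abundant entries took 5.27% of reads in the supplemented and 8.94% in the restricted library. Among the 4214 shortest loci, end minus start was a multiple of 3 in 91.4%, so the models of these loci hold mostly coding length. Longer loci were not checked.

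FPKM was summed over entries that share a gene name, which gave 15490 named genes, 1831 of them with more than 1 entry. The 4419 entries without a name were kept as separate genes and held 1.39% and 1.26% of reads. Of the names, 84.4% matched a symbol or synonym of the RefSeq annotation of ARS-UI_Ramb_v3.0, which was used for names only. Coordinates are those of the deposited table, written 1-based. Genes with a mean FPKM of at least 1 were called measured. The ratio is log2((supplemented FPKM + 1) / (restricted FPKM + 1)), which understates the difference of low genes, and genes at or beyond 1 or -1 were called higher or lower by size. Fold values are ratios of scaled reads with exact Clopper-Pearson 95% intervals from the recovered reads.

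No model over replicates could be fitted with 1 library per group. For 30 gene lists the median log2 ratio was set against 10000 random lists of the same size drawn from 20 bins of mean expression. A list stood apart below percentile 2.5 or above 97.5 with at least 5 measured members. Of the lists, 7 stood apart higher than their random lists, 8 lower and 13 did not, and 2 had too few members. Those higher include ribosomal protein genes (median -0.02) and autophagy and lysosome genes (median 0.01). Their medians lie near 0, so these lists are higher only against genes of like abundance. The named genes are the 12 with the largest ratio per direction among symbols with mean FPKM of at least 5 and a call in the deposited table, up to 4 members per list with the largest ratio, 10 genes of steroid, gonadotrophin and growth factor biology, and the 5 highest FPKM values per library. INHBB, CD74, CCL3 and CKM fall outside this rule and were named after their values were seen. Some genes that the rule selects are not reported here. The lists, the named-gene rule and the first set of alternatives were fixed before the data were examined. A further 4 lists (YAP and TEAD targets, striated muscle, NF-kappaB response, MHC class II) were added after.

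Alternatives covered pseudocounts of 0.1 and 5, no filter and a mean FPKM of at least 5, centring on the median of all measured genes, trimmed mean scaling (30% of ratios and 5% of abundances trimmed), ribosomal protein scaling, the most abundant entry per gene, and a threshold of 2 on the log2 ratio. Centring on the granulosa list, gene names with 1 entry, scaling each library to its share of all reads, and counting intervals wholly beyond 2-fold were added after seeing the data.

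The procedure was tested on simulated data for the supplemented against restricted comparison over 11927 genes. The size rule found 94% of 50 genes made 3-fold higher, 80% of 50 made 3-fold lower, 100% made 6-fold higher and 90% made 6-fold lower, and 1.83% of unchanged genes. Intervals covered the true ratio for 95.9% of unchanged genes and for 90% to 96% of the changed sets. The simulated reads held counting error only, with no spread between animals or from PCR, so this coverage is built in. Of 200 unchanged lists of 20 genes, 4.0% stood apart, and 100% of 50 lists shifted by 0.5 did. The unchanged lists were random genes ranked against random genes of the same ratios, so their low rate is also built in. It does not hold for lists of genes that vary together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.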

Results

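RNA was sequenced from granulosa cells of Hu sheep ewes kept on a high or a low feed allowance during the luteal phase of the oestrous cycle. Granulosa cells line the ovarian follicle, respond to follicle-stimulating hormone and make oestradiol and inhibin. The supplemented group (8 ewes) received 1.5 times the maintenance diet, 1560 g per ewe per day, and the restricted group (8 ewes) received 0.5 times, 520 g per ewe per day. Cells were scraped from the wall of all visible follicles above 2.5 mm in diameter. Each diet group is represented by 1 library, so there are no replicates, no spread between animals and no test of the diets. The supplemented library held 9426679 reads and the restricted library 11299773 reads over 22881 transcript entries, recovered from the deposited scaled values.

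The comparison addresses which genes of the granulosa cell layer differ between the 2 feed levels. The lists of leukocyte markers and of stromal markers were higher in the supplemented library, with medians of 1.96 and 0.61 on the log2 scale. The lists of granulosa cell identity genes and of cell cycle genes were lower, with medians of -0.53 and -0.72. TNF, a cytokine of activated macrophages, stood at 35.7 FPKM against 1.13, a 31.7-fold higher read ratio (95% counting interval 18.3 to 60.1). INHA, the inhibin alpha subunit, stood at 2910 FPKM against 7412, a 2.55-fold lower ratio (2.53 to 2.56). Of 11927 measured genes, 700 were at least 2-fold higher in the supplemented library and 340 were at least 2-fold lower on the log2(FPKM + 1) scale, so 67.3% of these genes were higher. With values centred on the granulosa cell genes that share was 92.8%, with each library scaled to its share of all reads it was 80.6% (both chosen after seeing the data), and at a mean FPKM of at least 5 it was 58.0%. Of the 700 higher genes, 529 had a counting interval wholly above 1, and of the 340 lower genes, 248 had an interval wholly below 1. For the rest, counting error alone leaves the direction unsettled. The direction of smaller differences depends on the scaling. As deposited, 4259 genes had a counting interval wholly below 1 and 2433 wholly above 1, with a median log2 ratio of -0.08 over all measured genes. By share of all reads 2313 lay below and 4209 above, with a median of 0.11. The authors' deposited table calls 140 entries up and 30 down in the supplemented library at q below 0.05. Its p and q values compare these 2 libraries, not the diets. Intervals cover counting error only, since reads of a PCR-amplified library are not independent molecules and animals add a spread that was not measured.

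**Figure D1:**
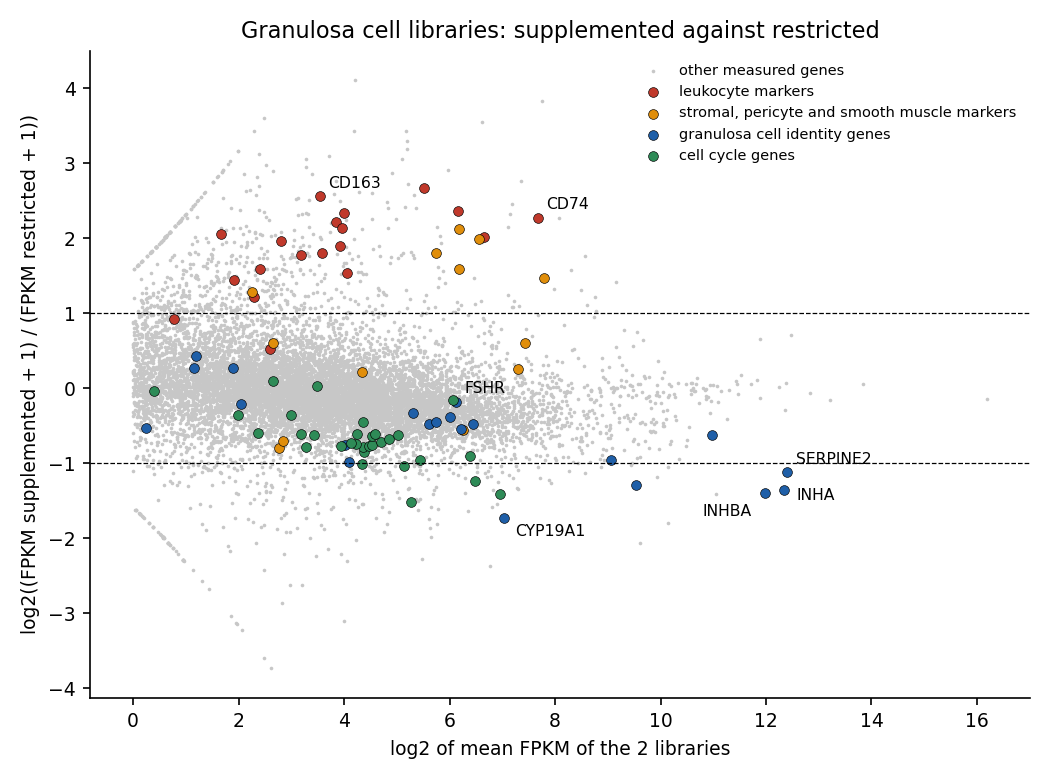
Each point is a measured gene, with log2 of its mean FPKM over the 2 libraries on the x axis and the log2 ratio of supplemented to restricted FPKM + 1 on the y axis. Dashed lines mark 2-fold. Of 19 leukocyte markers (red), 17 lie above the upper line, and INHA, INHBA and SERPINE2 lie below the lower line at the abundant end.

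TNF led the 12 genes with the largest higher ratio that the authors' deposited table also calls up. CXCL1, a neutrophil-attracting chemokine, stood at 406 FPKM against 27.5, a 15.2-fold ratio (12.9 to 17.9). IL8, another such chemokine, was 12.4-fold higher (8.83 to 18.0). The interleukin-1 genes followed, IL1A at 66.8 against 6.42 FPKM and IL1B at 112 against 14.0, which is 10.4-fold and 7.99-fold. S100A9 and S100A12, calcium-binding proteins of neutrophils and monocytes, were 12.7-fold and 15.1-fold higher. GPNMB, a glycoprotein of macrophages, was 14.1-fold higher, SAMSN1 21.0-fold and ABI3 16.2-fold. CARTPT, the precursor of the CART peptide, an inhibitor of oestradiol production in bovine granulosa cells, stood at 62.2 FPKM against 6.62 (109 against 12 reads, 9.40-fold, 5.17 to 18.8). PRL, the gene for prolactin, stood at 17.9 FPKM against 1.43 (193 against 16 reads).

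Among the 12 genes with the largest lower ratio, REG4, a secreted lectin, stood at 2.53 FPKM against 29.4, an 11.6-fold lower ratio (7.42 to 19.1). TFF2, a trefoil peptide, was 13.8-fold lower on 4 against 57 reads (5.09 to 52.2). S1PR1, a receptor for sphingosine 1-phosphate, was 8.90-fold lower. JAG1, a Notch ligand, was 5.83-fold lower and MMP1, a collagenase, 5.73-fold lower. GPX2, a glutathione peroxidase, stood at 34.5 against 183 FPKM. CTGF, a matricellular protein of growing follicles, stood at 303 against 1266 FPKM, a 4.18-fold lower ratio (4.04 to 4.33), and is located on chromosome 8 from 57077576 to 57108513 of Oar_v3.1. IGFBP1, an IGF-binding protein, was 4.76-fold lower. XIRP1, ANKH and OSAP were 5.22-fold, 3.72-fold and 3.59-fold lower.

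Genes of granulosa cell identity and gonadotrophin response were lower in the supplemented library as a group. The median log2 ratio of the 21 measured members was -0.53, at percentile 0.02 of 10000 random lists matched on expression, and 18 members were below 0. By size, 5 were lower and 0 higher. CYP19A1 (chromosome 7, 56126089 to 56212408), the aromatase that converts androgen to oestrogen, stood at 60.7 FPKM against 203, a 3.34-fold lower ratio (3.19 to 3.49). INHBA (chromosome 4, 79356028 to 79366930), the inhibin beta A subunit, stood at 2227 against 5880 FPKM, 2.64-fold lower (2.61 to 2.67). INHA is located on chromosome 2 from 220475905 to 220479941 and took 1.35% of all reads in the supplemented library against 2.98% in the restricted one. GJA1, the gap junction protein connexin 43, stood at 431 against 1057 FPKM, and SERPINE2, a protease inhibitor of follicular cells, at 3412 against 7419 FPKM (log2 ratio -1.12, but -0.91 and short of the size threshold by share of all reads). FSHR, the receptor for follicle-stimulating hormone, differed little, at 65.5 against 74.3 FPKM (log2 ratio -0.18, 0.03 by share of all reads, and 0.35 when centred on the granulosa list). LHCGR, the receptor for luteinising hormone, stood at 11.2 against 23.0 FPKM, 2.05-fold lower (1.83 to 2.31) but short of the size threshold on the log2(FPKM + 1) scale. The authors' deposited table calls CYP19A1 (q = 0.0131) and does not call INHA, INHBA, GJA1 or SERPINE2. Leukocyte markers were higher in the same library, with a median of 1.96.

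Steroid genes went in both directions and the list did not stand apart (8 measured, median -0.28, percentile 37.5, or -0.08 over 7 genes at a mean FPKM of at least 5). STAR, which carries cholesterol into mitochondria, stood at 61.5 FPKM against 17.2, a 3.57-fold higher ratio (3.1 to 4.11), and lies on chromosome 26 from 31960577 to 31966284. FDXR, a reductase in the electron supply of the mitochondrial steroid enzymes, stood at 71.4 against 171 FPKM, and HSD3B at 1.82 against 4.63 FPKM. CYP17A1, the androgen-making enzyme of theca cells, stood at 8.57 against 7.10 FPKM (1.00 to 1.46 as a ratio). CYP11A1 and HSD3B1, which the rule for named genes also covers, are not analysed here. Luteal cell markers did not stand apart either (6 measured, median -0.14, percentile 33.2), with a median that ran from -0.98 over 3 genes at a mean FPKM of at least 5 to 0.07 over 4 names with 1 entry, and the list shares STAR and HSD3B with the steroid genes.

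Markers of other cells that the follicle wall can hold were examined next. Of 19 measured leukocyte markers, 17 were at least 2-fold higher (median 1.96, or 1.30 with a pseudocount of 5) and the authors' deposited table calls 12 of them up. LAPTM5, a lysosomal protein of blood cells, stood at 79.9 against 11.7 FPKM, and CD163, a scavenger receptor of macrophages, at 20.7 against 2.66 FPKM. CD68 stood at 120 against 22.5 FPKM and CD14 at 27.3 against 4.60 FPKM. Stromal, pericyte and smooth muscle markers had a median of 0.61 over 13 genes (percentile 100), with 6 higher and 0 lower by size. COL1A2 and COL1A1, the chains of type I collagen, stood at 118 against 26.3 and 152 against 37.4 FPKM, and COL3A1 at 83.4 against 23.2 FPKM. MYH11, a smooth muscle myosin, stood at 109 against 35.7 FPKM. Theca markers had a median of 0.48 over 6 genes (percentile 99.2), but did not stand apart without a filter (0.20, percentile 91.3) or at a mean FPKM of at least 5 (0.28, percentile 94.9), with ENG at 6.59 against 1.90 FPKM and INSL3, a hormone of theca cells, at 201 against 93.7 FPKM. Endothelial and erythrocyte markers had 4 measured members each, too few for a call, with medians of 0.95 and 0.58. Without a filter the endothelial median was 0.21 over 13 genes (percentile 85.8), which did not stand apart, and the erythrocyte median was 0.31 over 6 genes (percentile 99.1), which did. PECAM1, an endothelial and leukocyte adhesion protein, stood at 10.4 against 1.79 FPKM. Oocyte markers were low in both libraries and had a median of -0.43 over 7 genes (percentile 0.56), which became 0.10 when centred on the granulosa list and did not stand apart at a mean FPKM of at least 5 (1 member). MOS, a kinase of the maturing oocyte, stood at 1.19 against 3.75 FPKM.

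Cell cycle genes were lower in the supplemented library. Their median was -0.72 over 31 measured members (percentile 0), 29 members were below 0, and 5 were lower by size. Centred on the granulosa list the median was -0.19. Leukocyte and stromal markers were higher in the same library, with medians of 1.96 and 0.61. CDK1, the kinase that drives mitosis, stood at 19.4 against 57.6 FPKM, and CCND2, the granulosa cell D-type cyclin, at 67.9 against 182 FPKM. UBE2C stood at 52.8 against 126 FPKM and BIRC5 at 22.8 against 47.8 FPKM. The authors' deposited table calls 0 of the 31 genes.

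Endoplasmic reticulum chaperones had a median of -0.64 over 19 genes (percentile 0.01), with 17 below 0 and 0 past the size threshold, and -0.11 when centred on the granulosa list. Leukocyte and stromal markers, with medians of 1.96 and 0.61, were higher in the same library as these chaperones and the metabolic lists that follow were lower. MANF and CRELD2 stood at 211 against 398 and 55.03 against 103 FPKM. Cholesterol synthesis and uptake genes had a median of -0.44 over 20 genes (percentile 0.47), and 0.09 when centred on the granulosa list. SC4MOL, a sterol oxidase, stood at 139 against 259 FPKM. Glycolysis genes had a median of -0.44 over 18 genes (percentile 0.64), and 0.09 when centred in that way, with SLC2A8 at 10.99 against 21.9 and PGK1 at 122 against 199 FPKM. Oxidative phosphorylation genes had a median of -0.39 over 80 genes (percentile 0.82), 0.14 when centred in that way, and did not stand apart over names with 1 entry (percentile 2.57). Of these genes 77 were below 0, 0 were lower by size and 2 were higher by size, both on few reads. COX6A2 stood at 2.79 FPKM (6 reads) and is listed at 0 in the restricted library, and COX7A2P2 stood at 2.39 against 0.385 FPKM (6 against 1 reads). NDUFB1 stood at 271 against 535 FPKM. Heat shock protein genes had a median of -0.46 over 15 genes (percentile 0.77), 0.07 when centred in that way, and did not stand apart over names with 1 entry (-0.34, percentile 9.03). HSPA1B stood at 12.7 against 40.2 FPKM and is called down in the authors' deposited table. Of the 15 heat shock genes, 12 were below 0 and 3 above, among them HSPB8 (log2 ratio 0.99) and HSPA6 (0.94).

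Extracellular matrix genes were higher in the supplemented library, with a median of 0.26 over 41 genes (percentile 100), 8 higher and 1 lower by size. The median was 0.06 over 63 genes without a filter and 0.50 over 27 genes at a mean FPKM of at least 5. The 36 members outside the stromal list had a median of 0.19. TIMP1, an inhibitor of matrix proteases, went the other way, at 505 against 1748 FPKM. Interferon-stimulated genes had a median of 0.47 over 15 genes (percentile 99.9), or 0.26 with a pseudocount of 5 and 1.01 over 7 genes at a mean FPKM of at least 5, with CXCL10 at 15.9 against 2.37 and ISG15 at 10.03 against 3.00 FPKM. Autophagy and lysosome genes had a median of 0.01 over 23 genes (percentile 99.6), or -0.02 over gene names with 1 entry. Their leading members were the cathepsins CTSZ, at 472 against 157 FPKM, and CTSB, at 827 against 308 FPKM. Ribosomal protein genes had a median of -0.02 over 73 genes and lay at percentile 100, since random lists of such abundant genes had medians between -0.39 and -0.15. That median became 0.06 when centred on all measured genes. Leukocyte markers, with a median of 1.96, were higher in the same library as the matrix and interferon genes.

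The remaining metabolic and signalling lists did not stand apart. Fatty acid synthesis and storage genes had a median of -0.10 over 21 genes (percentile 65.3), or -0.30 over 17 genes at a mean FPKM of at least 5, yet 4 members were higher by size. FABP5 and FABP4, fatty acid carriers, stood at 450 against 92.3 and 91.4 against 21.7 FPKM, CD36, a fatty acid receptor also present on macrophages, at 45.9 against 13.0 FPKM, and LPL at 5.71 against 2.16 FPKM. Fatty acid oxidation genes had a median of -0.14 over 21 genes (percentile 59.4), or -0.24 over 18 genes at that filter, with CPT1A, which admits fatty acids to mitochondria, at 9.32 against 2.88 FPKM. Insulin, IGF and metabolic hormone genes had a median of -0.09 over 21 genes (percentile 56.1), with LEPR, the leptin receptor, at 1.78 against 5.30 FPKM. IGF1 had 9 against 13 reads (ratio 0.72, 0.27 to 1.81), so a difference was not detectable at this depth. Antioxidant genes had a median of -0.36 over 24 genes (percentile 7.67), with GSTA1 at 1172 against 3099 FPKM. Pro-apoptotic genes had a median of -0.22 over 21 genes (percentile 18.0), or -0.10 over 23 genes without a filter, and anti-apoptotic genes -0.12 over 13 genes (percentile 58.5), with BCL2A1, an apoptosis inhibitor of leukocytes, at 34.0 against 4.68 FPKM. Amino acid and integrated stress response genes had a median of -0.14 over 19 genes (percentile 36.7), or -0.04 over 24 genes without a filter, with ATF3 at 30.4 against 12.7 FPKM.

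Immediate early genes (23 measured, median -0.29, percentile 13.3) and ovulatory genes (15 measured, median -0.16, percentile 16.7) split in direction, but at a mean FPKM of at least 5 the ovulatory genes stood apart lower (9 measured, median -0.59, percentile 0.08). MYC stood at 19.7 against 80.4 FPKM and FOS at 141 against 332 FPKM, while NR4A2 stood at 6.40 against 2.24 FPKM. PTGS2, the inducible cyclooxygenase of ovulation and inflammation, stood at 4.01 against 0.32 FPKM, and RUNX2 at 10.02 against 30.9 FPKM. TGF-beta superfamily genes (25 measured, median -0.11, percentile 36.1) included FSTL3 at 9.19 against 27.7 FPKM and TGFBR3 at 22.6 against 9.19 FPKM. Angiogenesis and hypoxia genes (17 measured, median 0.02, percentile 93.4) included THBS2 at 1.61 against 8.00 FPKM and NRP1 at 206 against 91.6 FPKM.

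**Figure D2:**
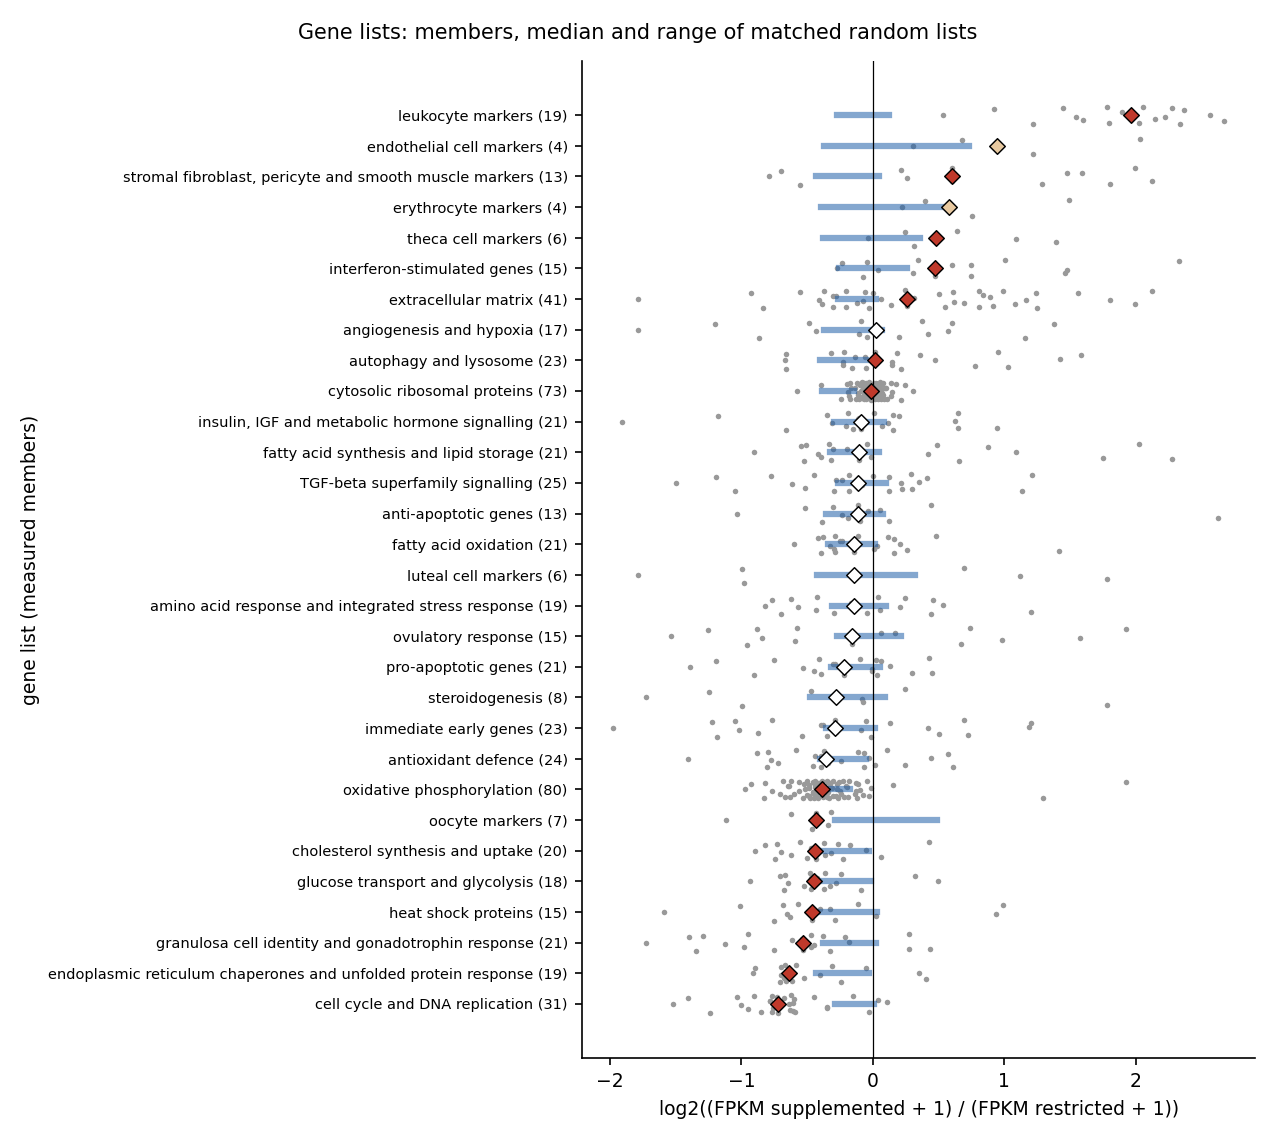
Gene lists fixed before the data were examined, with measured members in brackets. Grey points are members, diamonds are list medians on the log2 ratio axis (red, stands apart; white, does not; beige, too few members), and blue bars span the central 95% of medians of matched random lists. The leukocyte median lies at 1.96 and the cell cycle median at -0.72.

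Among the genes of highest FPKM, MT-CO3 stood at 71266 against 78360 FPKM, MT-CO1 at 14923 against 14364 and MT-ND4L at 9045 against 10021. MT-CO3 and MT-ND4L are placed on chromosome X in the deposited table, and whether they share reads with the mitochondrial genome was not tested. RPS29 stood at 7172 against 7458 FPKM. TES was among the 5 highest in the supplemented library, at 7101 against 4323 FPKM, and SERPINE2 was in the restricted library, at 3412 against 7419 FPKM (2.17-fold lower). FPKM divides by entry length, so this rank is not a rank by reads. In the supplemented library TES took 0.075% of reads and MT-CO3 0.49%, against 1.35% for INHA and 0.79% for SERPINE2.

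**Figure D3:**
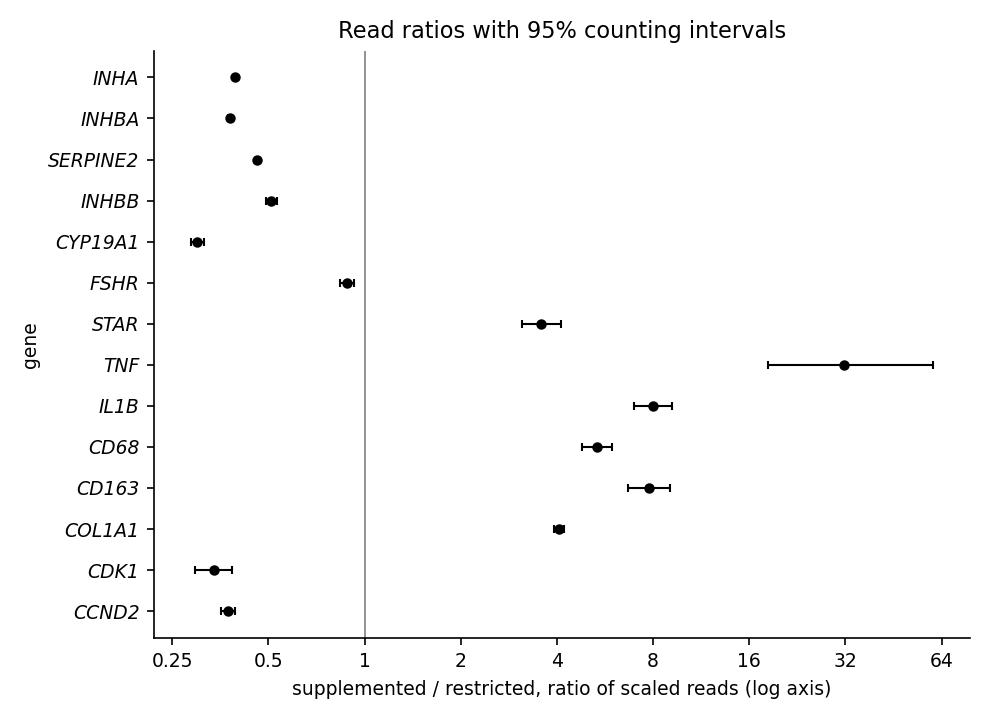
Ratio of scaled reads, supplemented over restricted, on a log axis for selected genes, with exact 95% intervals that cover counting error only. Intervals narrower than the point are hidden by it. INHA, INHBA, SERPINE2, INHBB, CYP19A1, FSHR, CDK1 and CCND2 lie below 1, and STAR, TNF, IL1B, CD68, CD163 and COL1A1 above 1.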

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

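Centring on the granulosa list, gene names with 1 entry, scaling by share of all reads and the counting-interval rule were chosen after seeing the data. The 700 higher and 340 lower genes became 228 and 132 with a pseudocount of 5, 302 and 219 at a mean FPKM of at least 5, 169 and 46 at a threshold of 2, and 405 and 149 with counting intervals wholly beyond 2-fold. Centred on the granulosa list they became 1657 and 129, since that centring moves every log2 ratio by 0.53 and the median of all measured genes to 0.45. Scaled by share of all reads, which raises log2 ratios by up to 0.21, they became 902 and 217, SERPINE2 was no longer 2-fold lower (-0.91), and the ribosomal median changed sign (0.19), as did 8 of the 15 lists that had not stood apart, all without a change of call. The authors' 140 up and 30 down entries became 71 and 7 at q at most 0.01. Under that centring the medians of cholesterol (0.0939), glycolysis (0.0852), oxidative phosphorylation (0.14), heat shock (0.0693), oocyte (0.10) and ribosomal protein genes (0.51) changed sign, by its construction, as did 12 lists that had not stood apart (0.17 to 0.44). The percentiles of these lists did not move with it. Under the same centring INHA, INHBA and SERPINE2 were no longer 2-fold lower (-0.82, -0.87 and -0.59), and CYP19A1 was (-1.19). The ribosomal median, close to 0, also changed sign when centred on all genes (0.0633), with trimmed mean scaling (0.0759), with ribosomal protein scaling (0.00255) and over names with 1 entry (0.00798). The lysosome median did so over names with 1 entry (-0.021). Over names with 1 entry, oxidative phosphorylation (-0.39, percentile 2.57) and heat shock genes (-0.34, percentile 9.03) no longer stood apart. Theca markers did not stand apart without a filter (0.20) or at a mean FPKM of at least 5 (0.28, 4 members), nor did oocyte markers at that filter (-0.34, 1 member). Ovulatory genes then stood apart (-0.59, percentile 0.08), as did erythrocyte markers without a filter (0.31, 6 members). Apart from the signs fixed by construction and the fewer members under a filter, the cause was not tested. Of 314 list values under alternatives, 295 kept their call with its sign, or stayed without a call. Of 524 values of single genes, 382 moved by no more than 0.5 of the width of their log2 counting interval, 142 moved by more and 0 called values changed sign. These totals leave out those 15 lists and 29 further named genes by share of all reads, of which 0 called values changed sign. Called values of single genes are past the size threshold, and a pseudocount cannot change their sign. The scalings and centrings move log2 ratios by at most 0.53. Only the use of the most abundant entry per gene could thus have changed a called sign. The alternative by the authors' test status was not run, as the table used here carries no status. Leaving out a library is impossible with 1 per group. Depth limits low genes most, as with 4 against 57 reads for TFF2.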

Other observations

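The tests in this part were all chosen after the results were seen, as were the NF-kappaB, MHC class II, striated muscle and YAP and TEAD lists. The other lists, and the trimmed mean and ribosomal protein scalings, were fixed before the data were examined. NF-kappaB response genes, a set of inflammatory targets, had a median log2 ratio of 1.79 over 25 measured genes, with 17 higher by size and 13 called up in the authors' deposited table. None of them is in the leukocyte list. The NF-kappaB list was chosen after the ratios were seen and holds TNF, so its median and counts are no independent support. CCL3, a macrophage chemokine, stood at 286 against 41.1 FPKM. MHC class II and antigen presentation genes had 4 measured members with a median of 2.30, led by HLA-DOA at 16.9 against 2.53 FPKM and LGMN at 236 against 46.3 FPKM, and 1 of them is also a leukocyte marker. Of the 138 genes the authors' deposited table calls up, 28 lie in the leukocyte, NF-kappaB or MHC class II lists. This count describes the called genes and tests nothing, since the NF-kappaB and MHC class II lists were chosen with the ratios in view.

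Leukocyte markers were higher in the supplemented library, with CD74, the most abundant of those named, at 341 against 69.4 FPKM. Ribosomal protein genes, whose median was -0.0154, did not share the rise, as a single scaling factor would require. The deposited values were already scaled per library, so a median near 0 was likely in advance. This is therefore only weak evidence against between-library scaling. A lower granulosa cell share that raised all other cell types alike would leave the leukocyte median close to theirs. The leukocyte median exceeded that of 34 theca, stromal, endothelial, erythrocyte and oocyte markers by 1.61 (95% bootstrap interval over genes 0.99 to 1.93). This comparison was computed in 3 versions. The first, against stromal markers alone, gave 1.36 (0.21 to 1.93) and did not reach the bound of 0.5 set for it. The pooled version was chosen after that and includes oocyte markers, whose own median was -0.43. Without the oocyte markers the pooled version gave 1.32 (0.58 to 1.75). Leukocyte markers rose more than the others in each version, but the versions differ on the bound, so an even rise was not decided. The bootstrap drew genes as if independent, though markers of a cell type can move together. Its intervals are therefore likely too narrow, and they cover no spread between libraries or animals. A lower share through added leukocytes alone would raise only leukocyte markers, and this comparison cannot address it. More leukocytes among the scraped cells, activation of resident cells, blood in the dissection and an effect of diet stay open and were not tested, with 1 library per diet.

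INHA, INHBA, CYP19A1 and SERPINE2 were lower in the supplemented library. Between-library scaling was examined with the trimmed mean, ribosomal protein and share of all reads scalings. The smallest fall of INHA, INHBA and CYP19A1 under them was -1.14, and that of SERPINE2 was -0.91, short of 2-fold. The 4 genes were split for this test after the value of SERPINE2 was seen. These scalings move log2 ratios by at most 0.21, so none of the 4 falls could have reached 0. Shifts of that size are too small to account for the falls, and a larger scaling error was not tested. Dilution of granulosa cell RNA by other cells stays open. The other 17 members of the granulosa list had a median of -0.47, but the 4 genes are among the 5 largest falls of that list, so the gap between them is set by the selection and decides nothing. Centring on the granulosa list left INHA at -0.82, INHBA at -0.87 and SERPINE2 at -0.59, all short of 2-fold, and CYP19A1 at -1.19. Diet and a different mix of follicle sizes also stay open and were not tested.

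Striated muscle genes were higher in the supplemented library, with a median of 1.34 over 14 measured genes. ACTA1, skeletal muscle actin, stood at 6.30 against 0.256 FPKM and MYLPF, a fast muscle myosin light chain, at 8.27 against 0.28 FPKM. Carry-over of striated muscle was not decided: of 22 listed muscle genes with 10 or more reads in total, 14 had a counting interval wholly above 1. An earlier version kept only genes under 1 FPKM in the restricted library, a filter that favours such intervals, and was dropped. CKM, a muscle creatine kinase, went the other way, at 21.1 against 35.7 FPKM.

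CTGF and CYR61 are targets of the YAP and TEAD regulators, and both were lower in the supplemented library, CYR61 at 26.6 against 83.1 FPKM. Whether such targets are lower as a group was not decided. The median of 19 measured targets was -0.00, at percentile 78.4 of matched random lists, with 9 above and 10 below 0, while 4 were lower by size, 0 were higher and the authors' deposited table calls 2 down.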
